A study of Mus musculus with 34 samples.

How the data were processed

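Spinal cord tissue of WT and KO mice was taken after sham surgery and 1, 3 and 7 days after spinal cord injury, and each of the 34 samples was hybridised to 1 Affymetrix array, per the labels. RNA was extracted with Trizol and biotinylated cRNA was prepared from 1 ug of RNA, per the labels' protocols. The deposited values are log2 probe set summaries made with GCRMA, per the submitters' processing notes, which state no version. GCRMA adjusts background by the GC content of the probes, normalises probes across arrays by quantiles and summarises each probe set by median polish. The deposited log2 values ran from 2.17 to 15.9, with 25.56% to 27.21% of the probe sets of an array at the shared floor and array medians from 4.138 to 4.391. They were used as deposited, with no further normalisation. No array's values equalled those of another.

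Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol in the annotation used here, 932 had several and 9160 had none. Symbols of 34741 were matched by Entrez ID to a gene table of assembly GRCm38.p6, which served only for names and for which genes neighbour Ntrk2. The array files name no genome build, so no coordinates are given. Each of 18193 genes was represented by its probe set with the highest mean over all arrays. Genes above log2 4 on at least 4 arrays were tested, which kept 11993 genes, from 20925 probe sets above that limit, and left out 6200. Low signal over background limits what arrays can show, so a gene left out is not shown to be unexpressed.

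Samples were grouped by genotype and time from the labels. Linear models with 1 mean per group were fitted to all 8 groups in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. There were 15 comparisons. They were each injured group against its sham group within genotype, KO against WT at each of 4 times, the genotype difference in the injury response at days 1, 3 and 7, and day 3 against day 1 and day 7 against day 3 as the mean over both genotypes. For Ntrk2, every probe set was tested, and its p-values were adjusted over all probe sets and, where stated, over the Ntrk2 probe sets alone. The slope between genotypes is the least squares slope of KO on WT log2 differences over the tested genes, and the counts by chance are the products of the 2 genotypes' shares.

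Before the data were examined, 28 gene lists with 525 entries were fixed, of which 480 entries were on the array, 1 through a synonym. They were cell cycle G1/S and DNA replication, cell cycle G2/M and mitosis, cell cycle inhibitors, homeostatic microglia, activated macrophage and phagocyte, neutrophil, cytokines and chemokines, complement, interferon response, lymphocyte, reactive astrocyte, homeostatic astrocyte, myelin and oligodendrocyte, oligodendrocyte precursor, cholesterol biosynthesis, neuron, neurotrophin signalling, endothelial, fibroblast and extracellular matrix, immediate early genes, iron and heme handling, heat shock and unfolded protein, red blood cell, Schwann cell and nerve root, skeletal muscle, ependymal, circadian clock, and sex-linked genes. Some genes are in more than 1 list, such as Lcn2 and Clcf1. The lymphocyte list had fewer than 3 tested genes and was not tested, which leaves 27. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, all in limma, and adjusted over the 27 lists of a comparison. Of 196 camera calls over all comparisons, 18 held with an estimated correlation. They were reactive astrocyte genes in WT at days 1 and 3 and in KO at days 1 and 7, activated macrophage and complement genes in WT at days 3 and 7 and in KO at day 7, cytokines and immediate early genes in KO at day 1, cholesterol biosynthesis in KO at day 7, the G2/M list in WT at day 3, in both comparisons between days and in KO against WT at day 1, and the G1/S list in KO against WT at day 1.

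The genes named were chosen by a rule fixed before any values were read. It takes, for each injury comparison, the 8 largest rises and 8 largest falls among genes that passed with no overlap between injured and sham arrays. From each list it takes up to 4 passing members with the smallest p, or the member with the smallest p if none passes. For KO against WT and the genotype difference in the injury response it takes up to 10 passing genes with the smallest p, or the 5 with the smallest p if fewer than 5 pass. It adds Ntrk2, Bdnf, Ngfr, Ccnd1, Pcna, Cdk1, Ccna2, Gfap, Aif1, Mbp and Snap25 in any comparison, the 5 largest rises and falls between days, and passing genes within 5 Mb of Ntrk2 or among the 20 nearest on either side. The rule names 350 genes. Genes named outside it, such as those of the glucocorticoid-responsive list, were chosen after their values were seen. Of 399 calls of a named gene that has another probe set above the filter, 7 had another probe set passing in the other direction, all for Clock and Eif2s3y.

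The fit was tested on simulated data made from the real arrays for KO against WT at day 1, in 5 runs with 200 changed genes of 11993. It recovered 59.2% of genes changed by log2 0.5, 91.6% of those changed by log2 1 and 97.5% of those changed by log2 2, and 4.48% of its calls were genes that had not been changed. A list of 11 genes shifted by log2 0.5 was called in all 5 runs, and 1 unshifted list was called. Only the mean and spread of each gene came from the real arrays, and genes were drawn independently. The simulation therefore cannot show how often camera calls lists wrongly when genes are correlated. Tables were joined with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

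Alternatives tried were a shift of every array to a common median, quantile normalisation, no intensity filter, a stricter filter at log2 6, the mean of all probe sets of a gene, every probe set by itself, the replicate number as a block, only the groups of a comparison in the fit, a trended and robust prior, array weights, and leaving out each array in turn. A further 4 alternatives were added after the data had been seen. Outlying arrays were tested with Dixon's ratio within each group, and other splits of the same arrays were counted for every comparison, with all splits where there were 35 and 100 drawn where there were more. Probe sets with several symbols or none were left out of the gene tests and tested apart. The p-value of the Hox rank correlation is from a permutation test.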

Results

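The series holds Affymetrix expression arrays of spinal cord tissue from wild-type (WT) mice and from mice without trkB.T1 (knockout, KO). TrkB.T1 is the truncated form of trkB, the receptor of brain-derived neurotrophic factor that Ntrk2 encodes, and it lacks the kinase domain. The mice had sham surgery that left the cord intact, or a spinal cord injury 1, 3 or 7 days before the tissue was taken. The 34 arrays form 8 groups, with 4 sham arrays of each genotype, 5 WT and 4 KO arrays at day 1, 4 WT and 5 KO arrays at day 3, and 4 arrays of each genotype at day 7. Log2 values of 45101 probe sets were deposited, and 11993 genes with signal above background were tested. The number of arrays limits the precision. The labels do not say that each array is a separate animal, so the p-values measure the spread between samples. A value after ± is the standard error of a log2 difference, or the SD of a group's level. A gene under log2 4 is not well above background. Where an array of the lower group is under it, a fold is given as at least, with values under 4 set to 4. A log2 difference is that of the deposited values, so its size stays open for such genes. The design asks which genes injury changes at each day in each genotype, how the days differ, and where the genotypes differ. The first principal component held 54.1% of the variance and set the sham arrays, at 72.3 ± 5.2 in WT and 71.3 ± 8.3 in KO (n = 4 each), apart from all injured groups. The means of the injured groups on this component ran from 7.9 ± 10.5, in KO at day 1 (n = 4), to -50.4 ± 24.6, in KO at day 3 (n = 5).

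Ntrk2, the targeted gene, is read by 8 probe sets. The probe sets that read low in KO cord, here called A and B, did so in every KO group. They were picked by these values, and which part of the transcript they read is not given here. Their agreement with the genotype labels is therefore no independent check, though an array that departs from its group still shows. Probe set A averaged 10.39 ± 0.21 in WT sham cord (n = 4), 10.20 ± 0.14 at day 1 (n = 5), 10.65 ± 0.15 at day 3 (n = 4) and 10.64 ± 0.16 at day 7 (n = 4). In KO cord it averaged 5.57 ± 2.68 (n = 4), 4.09 ± 0.45 (n = 4), 3.90 ± 0.72 (n = 5) and 4.18 ± 0.27 (n = 4) in the same order. Probe set B stood at 9.72 ± 0.11 in WT sham cord, and at 4.27 ± 2.88 in KO sham cord. At days 1, 3 and 7 it read 2.83 on every KO array, the lowest value it takes. The KO minus WT differences of these probe sets were -4.82 ± 0.69 and -5.45 ± 0.69 at sham, -6.11 ± 0.65 and -6.31 ± 0.66 at day 1, -6.76 ± 0.65 and -6.26 ± 0.66 at day 3, and -6.46 ± 0.69 and -6.91 ± 0.69 at day 7. All 8 differences passed over all probe sets tested, the least extreme at sham with adjusted p = 0.000667 and 0.000171 in limma. With only the sham groups in the fit, the sham differences did not pass, at adjusted p = 0.728 and 0.714. One library goes against its label. The library labelled KO sham replicate 2 read 9.46 and 8.59, against 4.28 ± 0.85 and 2.83 in the other 3 KO sham arrays. Without it the sham differences were -6.11 and -6.89. It was kept under its label, and it enters every comparison with KO sham cord described here.

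**Figure D1:**
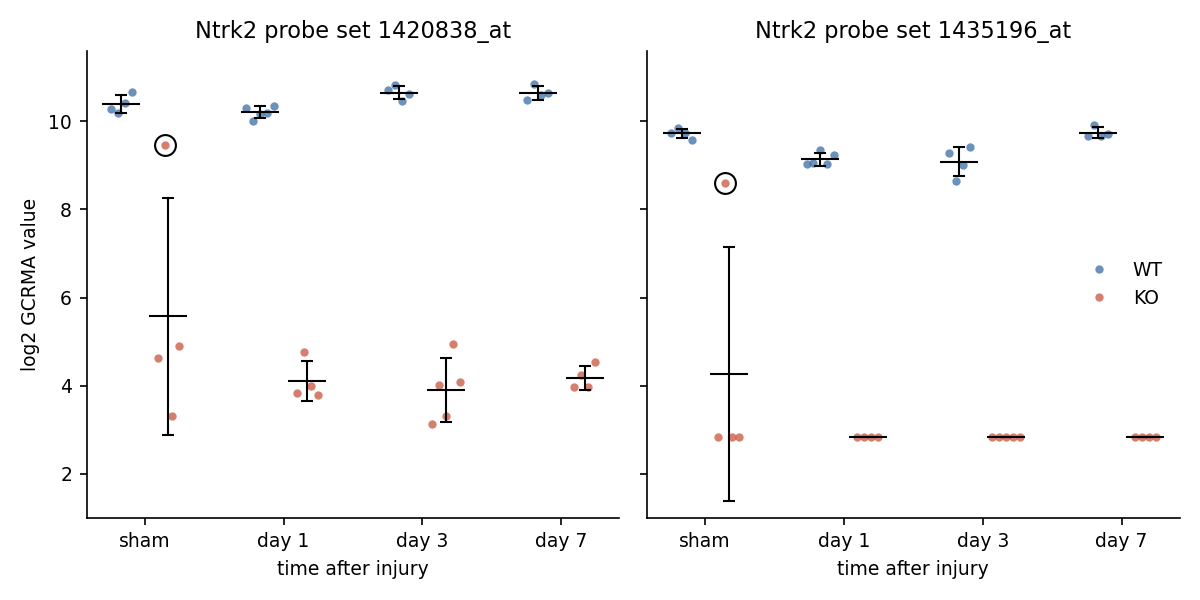
Log2 GCRMA value of Ntrk2 probe sets A (left) and B (right) on each of the 34 arrays, by time after injury, WT in blue and KO in red, with black bars at the group mean ± SD. The ringed point is the library labelled KO sham replicate 2, at 9.46 and 8.59, far above the other KO arrays. Every KO array, this one included, lies below every WT array.

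The other 6 Ntrk2 probe sets were neither lower nor higher in KO cord past the threshold over all probe sets. Which part of the transcript each of them reads is not given here, so they check nothing about the labels. The probe set with the highest signal stood at 11.10 ± 0.02 in WT sham and 11.31 ± 0.08 in KO sham cord (n = 4 each). Its KO minus WT difference was 0.612 ± 0.204 at day 1 and 0.631 ± 0.215 at day 7. Neither passed in limma over all probe sets, at adjusted p = 0.345 and 0.818. Adjusted over the Ntrk2 probe sets alone both passed, at adjusted p = 0.00925 and 0.00901. Of the other 6, those at 0.56 ± 0.18 and 0.61 ± 0.21 at day 1 also passed so (adjusted p = 0.0092 and 0.00998). The same probe sets passed so at day 7, at 0.66 ± 0.19 and 0.79 ± 0.22 (adjusted p = 0.00375 for both). These did not pass at sham or day 3. A probe set not above the filter was lower at day 7, at -0.50 ± 0.15 (adjusted p = 0.00407). With injury the probe set with the highest signal fell in WT cord by 0.97 ± 0.20 at day 1, 1.37 ± 0.21 at day 3 and 1.10 ± 0.21 at day 7. In KO cord its value at day 1 was -0.56 ± 0.21. In limma that value did not pass over all probe sets (adjusted p = 0.0611), but passed over the Ntrk2 probe sets alone (adjusted p = 0.0369). This probe set fell in KO cord by 1.35 ± 0.20 at day 3 and by 0.67 ± 0.21 at day 7. The genotype difference in the injury response was 0.41 ± 0.30 at day 1, with adjusted p = 1. Bdnf, which encodes the ligand of trkB, rose by 0.70 ± 0.27 in WT, a call lost in 5 of 34 fits with 1 array left out, and by 0.88 ± 0.29 in KO cord at day 1, and its KO minus WT difference there was 0.25 ± 0.27 (adjusted p = 0.824). With the caudal Hox mean as a covariate the WT value of Bdnf was -0.08, and with the mean of all probe sets the genotype difference of Ntrk2 at day 1 was -0.20. That mean takes in probe sets A and B, at -1.29 ± 0.94 and -0.86 ± 0.95. The other probe sets above the filter were at 0.30, 0.39, -0.13 and 0.41, so the turned sign does not describe them.

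At day 1 after injury, the genes that rose in WT cord included the following (5 injured and 4 sham arrays). Arg1, the arginase of alternatively activated macrophages, was at least 158-fold higher, a log2 difference of 8.77 ± 0.42. Timp1, an inhibitor of matrix metalloproteinases, was at least 105-fold higher (8.06 ± 0.24). Hmox1, which degrades heme, was at least 100-fold higher (7.42 ± 0.33). Ccl2, a monocyte attractant, was at least 55.6-fold higher (6.87 ± 0.30). Socs3, an inhibitor of cytokine signalling, was 101-fold higher (6.66 ± 0.26). Among the falls were Aplnr, the apelin receptor, at -3.75 ± 0.49, Dao, a D-amino acid oxidase, at -2.83 ± 0.17, and P2ry12, a purine receptor of resting microglia, at -2.80 ± 0.31.

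By gene list, all 24 tested reactive astrocyte genes rose in WT cord at day 1 (24 adjusted over the list alone), among them Serpina3n, a secreted protease inhibitor, 57.2-fold, and Tgm1, a transglutaminase, at least 41.4-fold. In the camera test this list kept its call with an estimated correlation, at adjusted p = 0.0199. Of the activated macrophage list, 22 of 25 genes rose (22 adjusted over the list alone), with Ms4a6d at least 54.4-fold and Fcgr2b, an inhibitory antibody receptor, 43.4-fold higher. Of the cytokines and chemokines, 19 of 21 rose (19 adjusted over the list alone), with Ccl12 at least 56.2-fold and Ccl3 at least 27.5-fold higher. Of the immediate early genes, 14 of 15 rose (14 adjusted over the list alone), with Atf3 at least 11.1-fold and Myc at least 13.1-fold higher. These 3 lists were called by camera at adjusted p = 9.21e-15, 5.75e-12 and 1.13e-11, and each missed the threshold narrowly, at adjusted p = 0.0525, with an estimated correlation. In the complement list 8 of 11 genes rose and 1 fell (the same counts adjusted over the list alone), with C3ar1, a receptor of a complement fragment, at least 22.7-fold higher (camera adjusted p = 8.36e-06, and adjusted p = 0.0794 with an estimated correlation). Interferon response genes rose in 15 of 20 cases (16 adjusted over the list alone), with Gbp2 15.8-fold higher (camera adjusted p = 2.6e-06, and adjusted p = 0.382 with an estimated correlation).

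Cell cycle genes also rose in WT cord at day 1. Of the G1/S and DNA replication list, 28 of 34 rose (28 adjusted over the list alone), with Mcm3, part of the replicative helicase, 11.3-fold and Ccnd1, cyclin D1, 4.25-fold higher. Of the G2/M and mitosis list, 17 of 36 rose (15 adjusted over the list alone), with Top2a, a DNA topoisomerase, at least 6.55-fold and Cdk1, the mitotic kinase, at least 4.89-fold higher. Camera called both at adjusted p = 1.17e-11 and 0.00129, and with an estimated correlation they had adjusted p = 0.157 and 0.471. The cell cycle is a topic of the study these arrays come from, so counts adjusted over its lists alone are not independent evidence. Neuronal genes fell in 16 of 25 cases (17 adjusted over the list alone), with the synaptic calcium sensor Syt1 at -1.51 ± 0.29 and the GABA-synthesising Gad1 at -1.13 ± 0.23. In the homeostatic astrocyte list 13 of 16 fell and 1 rose (the same adjusted over the list alone), with the gap junction gene Gja1 at -1.05 ± 0.15 and Aldh1l1 at 0.82 ± 0.12. Myelin and oligodendrocyte genes fell in 10 of 17 cases and rose in 2 (the same adjusted over the list alone), with Cnp at -0.56 ± 0.07. Camera called these 3 lists down at adjusted p = 0.00574, 0.0048 and 0.0251, and with an estimated correlation they had adjusted p = 0.578, 0.471 and 0.471. In all, 7140 of 11993 genes passed, 3248 higher and 3892 lower, and 1000 rose and 487 fell at least 2-fold.

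At day 3 after injury, mitotic genes rose in WT cord (4 injured and 4 sham arrays). Cdk1 was at least 27.6-fold higher (5.06 ± 0.21) and the cyclin Ccnb2 at least 19.5-fold higher (5.02 ± 0.24). Of the G2/M list, 35 of 36 genes rose (36 adjusted over the list alone), and of the G1/S list 30 of 34 rose and 1 fell (the same adjusted over the list alone), with the ribonucleotide reductase subunit Rrm2 21.3-fold higher. Camera called the G2/M list at adjusted p = 1.99e-23, and at adjusted p = 0.0407 with an estimated correlation. The G1/S list was called at adjusted p = 8.03e-13, and had adjusted p = 0.141 with an estimated correlation. Among phagocyte genes, Arg1 was at least 228-fold higher (9.30 ± 0.44), Hmox1 at least 194-fold (8.37 ± 0.34), and Gpnmb, a glycoprotein of lipid-laden phagocytes, at least 134-fold (8.14 ± 0.51). Of the activated macrophage list 24 of 25 genes rose (24 adjusted over the list alone), and of the complement list 9 of 11 rose and 1 fell (the same adjusted over the list alone), with C1qa 7.67-fold higher. Both kept their calls at adjusted p = 0.0407 with an estimated correlation, as did the reactive astrocyte list, of which 23 of 24 rose (23 adjusted over the list alone).

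Neuronal and lipid synthesis genes fell in WT cord at day 3. All 25 tested neuronal genes fell (25 adjusted over the list alone), with the potassium channel Kcnc1 at -1.49 ± 0.24 and Scn1a, a sodium channel, at -1.33 ± 0.23. Of the cholesterol biosynthesis genes 17 of 18 fell (17 adjusted over the list alone), with Msmo1 at -1.07 ± 0.10 and Fdft1, squalene synthase, at -0.86 ± 0.08. In the myelin list 15 of 17 fell and 1 rose (the same adjusted over the list alone), with the fatty acid hydroxylase Fa2h at -1.26 ± 0.20, and at -0.90 without WT day 3 replicate 2, whose myelin mean of 11.57 stood apart from 11.89 ± 0.01 on the other 3 arrays. Camera called these lists at adjusted p = 7.6e-06, 2.71e-07 and 0.0042, and with an estimated correlation they had adjusted p = 0.402, 0.152 and 0.402. Of the 13 tested neurotrophin signalling genes 8 fell and 1 rose (8 and 2 adjusted over the list alone), with Ntrk3, the receptor of neurotrophin-3, at -0.77 ± 0.15 (camera adjusted p = 0.0406, and adjusted p = 0.405 with an estimated correlation). Homeostatic microglia genes rose in 12 of 15 cases and fell in 1 (the same adjusted over the list alone), with the phagocytic receptor Trem2 9.37-fold higher, and with WT day 3 replicate 2 apart at a list mean of 7.36 from 8.59 ± 0.11 on the other 3 arrays (camera adjusted p = 9.54e-06, and adjusted p = 0.24 with an estimated correlation). Matrix genes of the fibroblast list rose in 18 of 20 cases (18 adjusted over the list alone), with Fn1, fibronectin, 15.7-fold higher (camera adjusted p = 2.34e-06, and adjusted p = 0.314 with an estimated correlation). In all, 8018 genes passed, 3533 higher and 4485 lower, and 1426 rose and 917 fell at least 2-fold.

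At day 7 after injury, the genes that rose in WT cord included Gpnmb, Cd5l, C3ar1 and Clec7a (4 injured and 4 sham arrays). Gpnmb was at least 693-fold higher (10.51 ± 0.51), Cd5l, a protein of tissue macrophages, at least 49.4-fold (7.30 ± 0.38), C3ar1 at least 80.5-fold (7.24 ± 0.25), and Clec7a, a receptor of fungal glucans, 123-fold (6.95 ± 0.37). Of the activated macrophage list 24 of 25 genes rose (24 adjusted over the list alone), and of the complement list 10 of 11 rose and 1 fell (the same adjusted over the list alone), with C1qc 21.1-fold higher. Camera called both at adjusted p = 2.62e-21 and 1.87e-09, and both kept the call, at adjusted p = 0.0261, with an estimated correlation. All 18 cholesterol biosynthesis genes fell (18 adjusted over the list alone), with Fdps, farnesyl diphosphate synthase, at -1.94 ± 0.14 and Msmo1 at -1.67 ± 0.10 (camera adjusted p = 6.73e-13, and adjusted p = 0.059 with an estimated correlation). Of the neuronal genes 24 of 25 fell (25 adjusted over the list alone), with Calb2, the calcium-binding calretinin, at -1.01 ± 0.17 and WT day 7 replicate 2 apart in the list's mean (camera adjusted p = 2.16e-05, and adjusted p = 0.394 with an estimated correlation). The G2/M list was higher in 28 of 36 genes (28 adjusted over the list alone), with Cdk1 at least 8.52-fold higher (camera adjusted p = 9.66e-12, and adjusted p = 0.198 with an estimated correlation). In all, 7088 genes passed, 3097 higher and 3991 lower, and 1285 rose and 483 fell at least 2-fold.

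In KO cord at day 1 (4 injured and 4 sham arrays, the library labelled KO sham replicate 2 among them), Arg1 was at least 160-fold higher (8.99 ± 0.44), Timp1 at least 86.5-fold (8.02 ± 0.26) and Hmox1 at least 65.8-fold (6.84 ± 0.34). All 24 reactive astrocyte genes rose (24 adjusted over the list alone; camera adjusted p = 0.0104 with an estimated correlation). Of the G1/S list 18 of 34 rose and 2 fell (the same adjusted over the list alone), with Mcm3 at least 6.9-fold and Ccnd1 2.93-fold higher (camera adjusted p = 7.46e-05, and adjusted p = 0.495 with an estimated correlation). Of the G2/M list 1 gene rose, Cdk1 at 0.70 ± 0.21, 1 fell, the mitotic kinesin Kif11 at -0.86 ± 0.36 (a call lost in 4 of 34 fits with 1 array left out), and 34 did not pass (none either way adjusted over the list alone), with camera adjusted p = 0.834. Cdk1 was under log2 4 on all 4 KO sham arrays and on 2 KO arrays at day 1. With values under 4 set to 4, Cdk1 rose by 0.13 and Kif11 fell by 0.52. Interferon response genes rose in 19 of 20 cases (20 adjusted over the list alone), with Gbp2 35.6-fold higher (camera adjusted p = 2.39e-12, and adjusted p = 0.147 with an estimated correlation). All 11 skeletal muscle genes fell (11 adjusted over the list alone), with Tnnc2, a troponin of fast muscle, at -6.34 ± 2.04 and Acta1, skeletal actin, at -5.40 ± 1.73 (camera adjusted p = 0.0126, and adjusted p = 0.606 with an estimated correlation). The mean log2 level of this list was 9.32 ± 1.25 in KO sham, 6.04 ± 3.12 in WT sham and 4.50 ± 1.44 in KO cord at day 1 (n = 4 each). In all, 6124 genes passed, 2846 higher and 3278 lower.

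KO cord at day 3 (5 injured and 4 sham arrays, the library labelled KO sham replicate 2 among them) had Arg1 at least 262-fold (9.70 ± 0.42), Clec4d, a lectin of myeloid cells, at least 87.5-fold (7.84 ± 0.33) and Cdk1 at least 34.1-fold higher (5.68 ± 0.20). All 36 G2/M genes rose (36 adjusted over the list alone) and 31 of 34 G1/S genes rose and 1 fell (the same adjusted over the list alone). Camera called these lists at adjusted p = 8.41e-24 and 5.73e-14, and with an estimated correlation they had adjusted p = 0.0599 and 0.112. All 25 neuronal genes fell (25 adjusted over the list alone), with the GABA transporter Slc32a1 at -1.63 ± 0.21 (camera adjusted p = 7.25e-07, and adjusted p = 0.346 with an estimated correlation). In all, 8359 genes passed, 3709 higher and 4650 lower. At day 7 (4 injured and 4 sham arrays) Gpnmb was at least 651-fold higher (10.10 ± 0.51) and Cd36, a lipid scavenger receptor, at least 63.5-fold (6.85 ± 0.61). The activated macrophage list rose in 23 of 25 genes (23 adjusted over the list alone), complement in 10 of 11 with 1 fall (the same adjusted over the list alone), and all 18 cholesterol biosynthesis genes fell (18 adjusted over the list alone), with Stard4, a sterol carrier, at -1.76 ± 0.13. With an estimated correlation camera called them at adjusted p = 0.0137, 0.0137 and 0.0451. Muscle genes fell in 10 of 11 cases (10 adjusted over the list alone), with Myh4, a fast myosin, at -6.41 ± 1.87 (camera adjusted p = 0.0265, and adjusted p = 0.556 with an estimated correlation), and the list's mean level at day 7 was 4.59 ± 0.57 (n = 4). In all, 6540 genes passed, 2824 higher and 3716 lower.

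**Figure D2:**
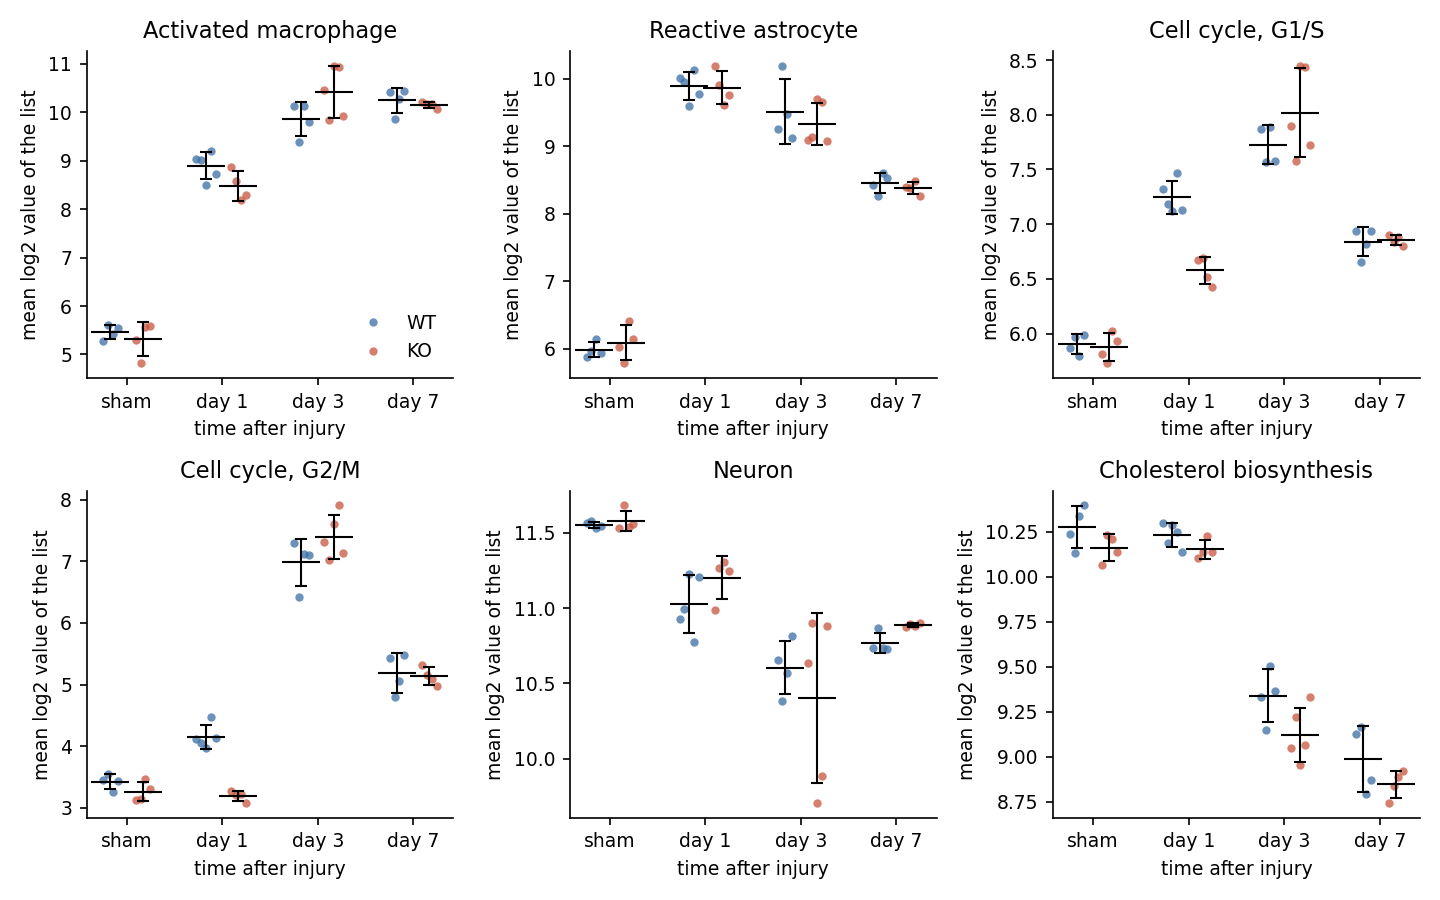
Mean log2 value of 6 gene lists on each of the 34 arrays, by time after injury, WT in blue and KO in red, with black bars at the group mean ± SD. The G2/M list averaged 3.42 in WT sham cord, 4.15 at day 1, 6.99 at day 3 and 5.19 at day 7, and 3.26, 3.19, 7.40 and 5.14 in KO cord.

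Injury moved largely the same genes the same way in both genotypes, a comparison that shares no arrays between them. At day 1, 2497 genes passed as higher in both genotypes and 2795 as lower in both, against 770.8 and 1063.8 by chance, and 2 passed in opposite directions. The genes higher in both included Socs3, by 6.66 ± 0.26 in WT and 6.35 ± 0.27 in KO cord, and Serpina3n, by 5.84 ± 0.13 and 5.70 ± 0.14. At day 3 the counts were 3171 and 4026, against 1092.6 and 1739 by chance, with 3 opposite. At day 7 they were 2588 and 3238, against 729.3 and 1236.6 by chance, with 2 opposite. Across genes, which are not independent replicates, the slope of the KO on the WT log2 response was 0.887 at day 1, 1.04 at day 3 and 0.917 at day 7, with r = 0.918, 0.956 and 0.942.

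From day 1 to day 3, over both genotypes, proliferation genes rose and early cytokine genes fell (9 arrays at each day). Ccnb2 rose at least 20-fold (4.96 ± 0.16), Aspm, a spindle pole protein, at least 11.8-fold and Gpnmb at least 29.1-fold (4.88 ± 0.34). The falls included the neutrophil attractant Cxcl3 at -4.32 ± 0.45, the cytokine Il6 at -3.22 ± 0.44 and the acute phase gene Saa1 at -2.95 ± 0.34. All 36 G2/M genes rose (36 adjusted over the list alone), and the list was called at adjusted p = 0.014 with an estimated correlation. Of the cytokines and chemokines 15 of 21 fell and 2 rose (17 and 2 adjusted over the list alone), with Cxcl10 at -2.14 ± 0.30 (camera adjusted p = 0.00804, and adjusted p = 0.444 with an estimated correlation). All 18 cholesterol biosynthesis genes fell (18 adjusted over the list alone), with Fdft1 at -1.12 ± 0.06 (camera adjusted p = 5.31e-13, and adjusted p = 0.0683 with an estimated correlation). All 11 skeletal muscle genes rose (11 adjusted over the list alone), with Tnni2 at 3.82 ± 1.09 (camera adjusted p = 0.018, and adjusted p = 0.579 with an estimated correlation), where the list's level on single KO arrays at day 3 ran from 4.48 to 13.54. In all, 7242 genes passed, 3129 higher and 4113 lower.

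From day 3 to day 7 mitotic genes fell, over both genotypes (9 and 8 arrays). Mcoln3, a lysosomal channel, rose at least 4.92-fold (3.65 ± 0.12), Atp6v0d2, a proton pump subunit, at least 12.9-fold (4.36 ± 0.24) and the elastase Mmp12 at least 14.5-fold (4.14 ± 0.43). Arg1 fell by 3.72 ± 0.30, Hmox1 by 3.81 ± 0.24 and Ccl2 by 3.60 ± 0.22. Of the G2/M list 35 of 36 genes fell (36 adjusted over the list alone), with the kinesin Kif20a at -3.30 ± 0.16, and the list was called at adjusted p = 0.0189 with an estimated correlation. Of the G1/S list 30 of 34 fell and 1 rose (the same adjusted over the list alone), with Tk1, thymidine kinase, at -2.76 ± 0.21 (camera adjusted p = 6.15e-19, and adjusted p = 0.0821 with an estimated correlation). Reactive astrocyte genes fell in 18 of 24 cases (19 adjusted over the list alone), with Timp1 at -2.25 ± 0.18 (camera adjusted p = 6.02e-10, and adjusted p = 0.124 with an estimated correlation). Neuronal genes rose in 14 of 25 cases (16 adjusted over the list alone), with Nefh, a neurofilament, at 0.42 ± 0.12 (camera adjusted p = 0.00331, and adjusted p = 0.662 with an estimated correlation). In all, 5535 genes passed, 2977 higher and 2558 lower.

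Between the genotypes after sham surgery, 8 genes passed, 7 higher and 1 lower in KO cord (4 arrays each, the library labelled KO sham replicate 2 among the KO arrays). Of these, 4 were Hox genes of caudal position, Hoxd10 at 5.51 ± 1.08, Hoxa10 at 2.61 ± 0.35, Hoxc10 at 1.81 ± 0.27 and Hoxd9 at 1.33 ± 0.26, with adjusted p from 0.000191 for Hoxa10 to 0.0352 for Hoxd9. With 1 array left out the calls of Hoxd10 and Hoxd9 were lost in 7 and 6 of 34 fits, and those of Hoxa10 and Hoxc10 in 0. Also higher were Cd59a, an inhibitor of complement lysis, at 0.87 ± 0.11 (adjusted p = 0.000191), Egr2, a transcription factor of myelinating Schwann cells, at 2.19 ± 0.37, and Slc39a8, a zinc importer, at 0.96 ± 0.17. Slc34a3, a phosphate transporter, was lower at -0.80 ± 0.15. The call of Egr2 was lost in 1 such fit, and those of Slc39a8 and Slc34a3 in 4 each. The library labelled KO sham replicate 2 had Cd59a at 9.70, between 9.17 ± 0.03 in WT sham and 10.16 ± 0.03 in the other 3 KO sham arrays. No skeletal muscle gene passed (0 of 11, and 0 adjusted over the list alone), with Acta1 at 3.65 ± 1.73 (adjusted p = 1), while camera called the list higher at adjusted p = 1.56e-08, and at adjusted p = 0.535 with an estimated correlation. The Schwann cell list, of which 0 of 7 genes passed (2 adjusted over the list alone), was called higher at adjusted p = 1.61e-06, and had adjusted p = 0.279 with an estimated correlation. The endothelial list, of which 0 of 13 passed (0 adjusted over the list alone), was called higher at adjusted p = 1.56e-08, and also had adjusted p = 0.279 with an estimated correlation. Camera called 4 lists lower in KO sham cord, each with 0 genes passing and 0 adjusted over the list alone. They were cholesterol biosynthesis (adjusted p = 5.97e-05), G2/M (adjusted p = 0.00181), activated macrophage (adjusted p = 0.0285) and complement (adjusted p = 0.0485). With an estimated correlation the first had adjusted p = 0.704 and the others adjusted p = 0.827. A lower G2/M list in KO cord was thus also called without injury. Its mean was 3.42 ± 0.12 in WT sham and 3.26 ± 0.16 in KO sham cord (n = 4 each). Both lie under log2 4, so this call compares values that are not well above background. With the caudal Hox mean as a covariate the G2/M list (adjusted p = 0.0903), the macrophage list (adjusted p = 0.000219) and the complement list (adjusted p = 0.0275) turned upward. Without WT sham replicate 4, or without KO sham replicate 4, 4 genes passed, with array weights 65, without the intensity filter 22, with every probe set tested 13, with the caudal Hox mean as a covariate 867, and with only the sham groups in the fit 1.

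**Figure D3:**
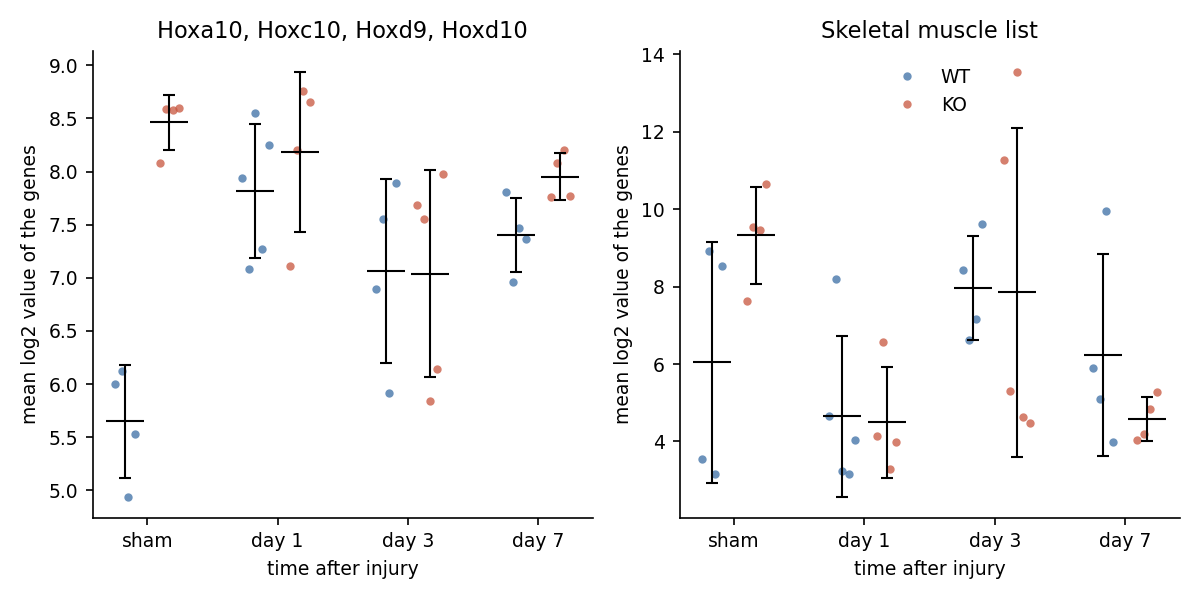
Mean log2 value of Hoxa10, Hoxc10, Hoxd9 and Hoxd10 and of the skeletal muscle list on each of the 34 arrays, by time after injury, WT in blue and KO in red, with black bars at the group mean ± SD. The Hox mean was 5.65 ± 0.54 in WT sham cord and 8.46 ± 0.25 in KO sham cord (n = 4 each), and from 7.04 to 8.18 in the 6 injured groups.

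At day 1 after injury, cell cycle genes were lower in KO than in WT cord (4 KO and 5 WT arrays). Top2a was at -2.88 ± 0.27 on the log2 scale, at least 6.99-fold lower, Pbk, a mitotic kinase, at -2.72 ± 0.30, Rrm2 at -2.41 ± 0.27, Birc5, the mitotic survivin, at -2.40 ± 0.28, and Cdk1 at -2.20 ± 0.20. Cep55, which acts in abscission, was at -2.32 ± 0.23, Ccna2, cyclin A2, at -2.30 ± 0.23, Cdca5, a regulator of cohesion, at -2.25 ± 0.21, and Cdca8, of the chromosomal passenger complex, at -2.01 ± 0.25. All 9 had adjusted p of 9.97e-06 or less in limma, the value of Cdca8. All 4 KO arrays were under log2 4 for Cdca5 and Cep55, and 3 for Pbk, Birc5, Ccna2 and Cdca8. For Cdk1 it was 2 arrays and for Top2a 1, so the size of these differences stays open. With values under 4 set to 4, Cdca5 was at least 2.34-fold, Ccna2 at least 3.91-fold and Cdk1 at least 4.51-fold lower. Ccnd1 was lower by less, at -0.53 ± 0.13 (adjusted p = 0.037), a call lost in 6 of 34 fits with 1 array left out, and Pcna did not pass, at -0.32 ± 0.09 (adjusted p = 0.122). Of the G1/S list 10 of 34 genes were lower (25 adjusted over the list alone), and of the G2/M list 14 of 36 (19 adjusted over the list alone), with no gene of either higher. Camera called both, at adjusted p = 8.13e-33 and 9.05e-35, and at adjusted p = 0.0125 for both with an estimated correlation. Fry, which tests whether a list's genes move on balance one way, gave adjusted p = 0.000707 and 0.000546. The G1/S list averaged 6.58 ± 0.13 in KO and 7.24 ± 0.15 in WT cord (n = 4 and 5). The G2/M list averaged 3.19 ± 0.08 and 4.15 ± 0.19. Its KO mean is under log2 4, so the size of its difference stays open. The cell cycle was a topic of the study, so the counts adjusted over these lists alone are not independent evidence.

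**Figure D4:**
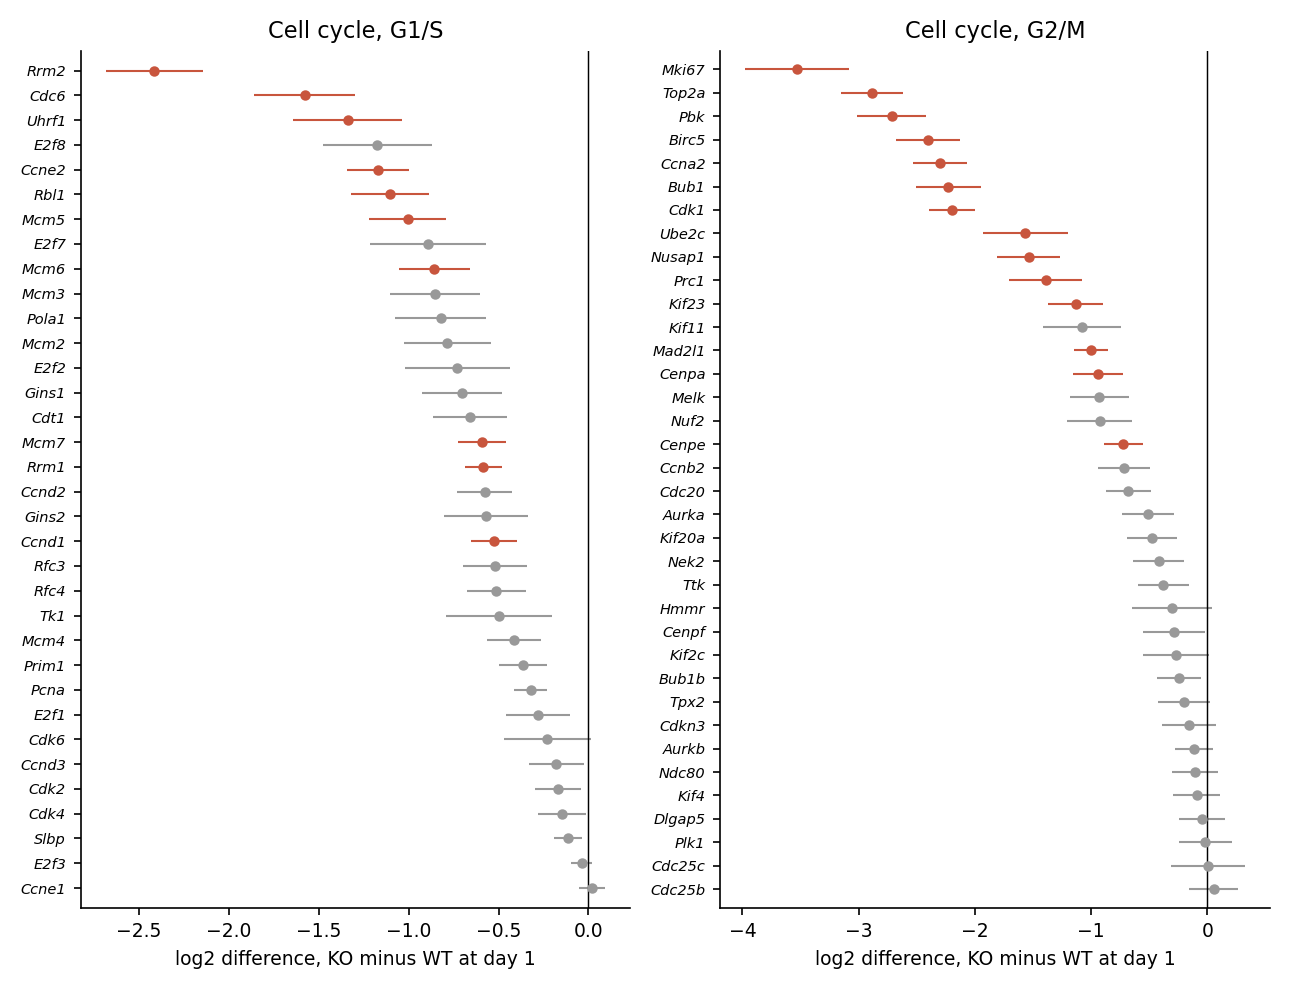
Log2 difference between KO and WT cord at day 1 (4 and 5 arrays) for the 34 tested G1/S genes and the 36 tested G2/M genes, points with their standard errors, genes past the threshold in red and others in grey. Red points mark 10 and 14 genes, all lower in KO, with Rrm2 at -2.41 and Top2a at -2.88.

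Outside the cell cycle, Cd59a was higher in KO cord at day 1 by 0.86 ± 0.11 (adjusted p = 1.01e-05), as was Dapk1, a death-associated kinase, by 0.95 ± 0.13 (adjusted p = 8.82e-05). Dapk1 lies near Ntrk2 on the GRCm38.p6 gene map, with 15 other tested genes nearer. It was the only gene among the 69 tested within 5 Mb of Ntrk2 to pass at any of the 4 time points, where Ntrk2 itself was read by its probe set with the highest signal and not by A or B. At sham Dapk1 was also higher in KO cord, by 0.66, but did not pass in limma (adjusted p = 0.0765). There the library labelled KO sham replicate 2 read 7.04, against 7.37 ± 0.07 in the other KO sham arrays and 6.62 ± 0.29 in WT sham. The clock genes Npas2 and Arntl were higher by 0.94 ± 0.17 and 0.47 ± 0.11, the call of Arntl being lost in 6 of 34 fits with 1 array left out, and of the 12 clock genes these 2 passed (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.993). Stat2, which transduces interferon signals, was higher by 0.90 ± 0.19 (adjusted p = 0.0102, lost in 2 of these fits), the 1 of 20 interferon response genes to pass, with 12 higher adjusted over the list alone. Camera called that list at adjusted p = 1.68e-12, it had adjusted p = 0.331 with an estimated correlation, and fry gave adjusted p = 0.089. Cxcl10, a chemokine induced by interferon, was higher by 1.74 ± 0.43 (adjusted p = 0.0429), but the call was lost in 20 of 34 fits with 1 array left out. Its lowest value in these fits was 1.155, without KO day 1 replicate 1. Fcrls, a microglial receptor, was lower at -0.93 ± 0.21, lost in 4 of these fits, and 1 of 15 homeostatic microglia genes passed (7 lower adjusted over the list alone; camera adjusted p = 6.47e-06, and adjusted p = 0.413 with an estimated correlation). Cdkn2c, an inhibitor of cyclin-dependent kinases, was lower at -0.83 ± 0.19, lost in 6 of these fits, 1 of 13 inhibitor genes to pass (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.993).

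Camera called 7 further lists between the genotypes at day 1, with 0 genes passing in each. Lower in KO cord were activated macrophage (adjusted p = 4.44e-05, and adjusted p = 0.476 with an estimated correlation; 2 lower adjusted over the list alone), complement (0.00677 and 0.413), fibroblast and extracellular matrix (0.00726 and 0.725), myelin and oligodendrocyte (0.0383 and 0.725) and cholesterol biosynthesis (0.0428 and 0.725). Higher were neuron (0.0193 and 0.795) and neurotrophin signalling (0.0294 and 0.556). Except for the first list, 0 genes passed adjusted over the list alone. KO day 1 replicate 3 stood apart in the myelin list and KO day 1 replicate 1 in the neurotrophin list. The macrophage list averaged 8.48 ± 0.30 in KO and 8.90 ± 0.28 in WT cord, and the fibroblast list 8.40 ± 0.59 and 8.91 ± 0.11 (n = 4 and 5).

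In all, 103 genes passed between the genotypes at day 1, 23 higher and 80 lower in KO, and 38 of the lower ones, Top2a and Cdk1 among them, by at least 2-fold. The count was 55 without WT day 1 replicate 4, 63 without KO day 1 replicate 3, 49 without KO day 1 replicate 4 and 208 without WT day 3 replicate 2. It was 166 with the replicate number as a block, 310 with array weights, 259 without the 2 arrays farthest from their groups, and 65 with only these groups in the fit.

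At day 3 after injury, 4 genes passed between the genotypes (5 KO and 4 WT arrays). Cd59a and Dapk1 were higher in KO cord, by 0.91 ± 0.11 (adjusted p = 3.36e-05) and 0.99 ± 0.13 (adjusted p = 0.000281). Nkd1, an inhibitor of Wnt signalling, was lower at -0.59 ± 0.11, and Insig1, which holds back sterol synthesis, at -0.52 ± 0.10 (adjusted p = 0.0423 for both). With 1 array left out their calls were lost in 23 and 22 of 34 fits. No cell cycle gene passed, with Cdk1 at 0.29 ± 0.20 (adjusted p = 0.557) and Ccna2 at 0.47 ± 0.23 (adjusted p = 0.437). With array weights the value of Cdk1 was -0.09. Camera called the G1/S and G2/M lists higher in KO, at adjusted p = 2.06e-08 and 6.92e-10, with 0 of 34 and 0 of 36 genes passing (2 and 4 higher adjusted over the list alone). With an estimated correlation both had adjusted p = 0.348, and fry gave adjusted p = 0.142 and 0.141. Of the cholesterol biosynthesis list 1 of 18 genes was lower (7 adjusted over the list alone; camera adjusted p = 2.06e-08, and adjusted p = 0.348 with an estimated correlation). The neuron and clock lists, called lower at adjusted p = 0.000309 and 0.0173, had adjusted p = 0.704 and 0.348 with an estimated correlation, and with array weights both pointed the other way. In all, camera called 11 lists between the genotypes at day 3, 7 higher and 4 lower in KO. With an estimated correlation it called 0. Leaving out 1 of the 34 arrays moved the count of 4 by over 1.5 times in 23 cases, to 14 without WT day 3 replicate 1, 32 without KO day 3 replicate 2, 14 without KO day 3 replicate 5, and 2 in the rest. With array weights, after the shift to a common median, or without the 2 arrays farthest from their groups, 2 genes passed, with the caudal Hox mean as a covariate 11, and with only these groups in the fit 0.

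At day 7 after injury, 4 genes passed between the genotypes (4 arrays each). Cd59a and Dapk1 were again higher in KO cord, by 0.91 ± 0.11 (adjusted p = 8.5e-05) and 1.00 ± 0.14 (adjusted p = 0.000715). Mcoln3 was lower at -0.91 ± 0.17 (adjusted p = 0.0464) and the calpain Capn6 at -0.71 ± 0.14 (adjusted p = 0.0492), calls that were lost in 23 and 26 of 34 fits with 1 array left out. The interferon response list was called higher in KO by camera at adjusted p = 2.32e-05, with 0 of 20 genes passing (0 adjusted over the list alone), and had adjusted p = 0.619 with an estimated correlation. It was among 6 lists that camera called at day 7, 2 higher and 4 lower in KO, of which 0 were called with an estimated correlation. The cell cycle lists were not called, at adjusted p = 0.827 for G1/S and 0.297 for G2/M, with 0 genes of either passing. Leaving out 1 array moved the count of 4 by over 1.5 times in 20 of 34 cases, to 9 without KO day 3 replicate 4 and to 2 in the rest. It was 233 with array weights, 21 with only these groups in the fit, 10 with every probe set tested, 9 without the intensity filter, 8 without the 2 arrays farthest from their groups, and 2 with the replicate block, the trended prior or the muscle covariate.

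The test of the genotype difference in the injury response asks whether KO and WT cord changed by different amounts from their own sham groups, the library labelled KO sham replicate 2 included. At day 1, 17 genes passed, and all 17 had the smaller or more negative response in KO. They included Cdca5 at -2.38 ± 0.31 (adjusted p = 0.00029), Cep55 at -2.32 ± 0.33, Top2a at -2.62 ± 0.39, Cdk1 at -1.86 ± 0.29, Pbk at -2.71 ± 0.44, Ccna2 at -2.04 ± 0.34, and Slc39a8 at -1.50 ± 0.24. Ect2, which drives cytokinesis, was at -1.71 ± 0.31 and Pclaf, a partner of PCNA, at -2.11 ± 0.39. All 4 KO arrays at day 1 were under log2 4 for Cdca5 and Cep55, so the size of their differences stays open. Of the G1/S list 1 gene was lower (15 adjusted over the list alone), Rrm2 at -1.88 ± 0.39, whose call was lost in 14 of 34 fits with 1 array left out. Of the G2/M list 5 were lower (14 adjusted over the list alone). Camera called both lists at adjusted p = 1.02e-20 and 3.07e-18, and both had adjusted p = 0.166 with an estimated correlation. The count was 28 without the library labelled KO sham replicate 2, with 16 of the 17 genes among them, and 38 without WT day 3 replicate 2. It was 105 with array weights, 45 without the 2 arrays farthest from their groups, 10 with the mean of all probe sets, and 1346 with the caudal Hox mean as a covariate.

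At day 3 no gene passed the test of the genotype difference in the injury response in limma, and 839 had an unadjusted p under 0.05. Hoxa10 came closest, at -2.45 ± 0.48 with adjusted p = 0.228, and Plcg2, a phospholipase of immune cell signalling, was at 1.16 ± 0.24 with the same adjusted p. The activated macrophage list was called higher by camera at adjusted p = 1.12e-08, with 0 of 25 genes passing (6 adjusted over the list alone), and had adjusted p = 0.265 with an estimated correlation. With the caudal Hox covariate that list pointed the other way. One gene passed without WT day 3 replicate 3, and likewise 1 without the library labelled KO sham replicate 2, and 3 without the intensity filter. At day 7, 1 gene passed, Cnmd, which encodes the cartilage protein chondromodulin, at -1.93 ± 0.31 (adjusted p = 0.00935). The endothelial list, with 0 of 13 genes passing (2 lower adjusted over the list alone), was called lower at adjusted p = 4.08e-08, and had adjusted p = 0.488 with an estimated correlation. Without WT day 7 replicate 2, or without the library labelled KO sham replicate 2, 2 genes passed, with array weights 56, with only these groups in the fit 57, with the caudal Hox covariate 146, without the intensity filter 4, and with the stricter filter 0.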

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

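The 9 tests of 3 patterns described in this part were chosen only after the results they weigh had been seen, while the splits of arrays were planned before. Outlying arrays were looked for with Dixon's ratio in every group, where about 1 in 20 groups stands out by chance.

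In the means of gene lists, 15 of 216 groups had an outlying array. The library labelled KO sham replicate 2 stood apart in the cell cycle inhibitor list (7.851), the complement list (5.319) and the neuron list (11.681). WT day 3 replicate 2 stood apart in 5 lists, homeostatic microglia (7.36), homeostatic astrocyte (10.504), myelin and oligodendrocyte (11.569), oligodendrocyte precursor (8.651) and ependymal (5.398). The others were WT sham replicate 2 in homeostatic microglia (6.594), KO day 7 replicate 1 in cytokines and chemokines (5.424), KO day 1 replicate 3 in myelin and oligodendrocyte (12.018), WT day 7 replicate 2 in neuron (10.869), KO day 1 replicate 1 in neurotrophin signalling (8.907), KO sham replicate 1 in heat shock and unfolded protein (9.909) and KO day 7 replicate 3 in Schwann cell and nerve root (6.991). None was left out of the comparisons.

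In the Ntrk2 probe sets, 10 of 53 groups had an outlying array. The named ones were the library labelled KO sham replicate 2 in probe set B (8.593), WT sham replicate 2 (11.14) and KO day 1 replicate 1 (10.438) in the probe set with the highest signal, KO day 1 replicate 1 in 2 others (9.816 and 3.363) and WT day 1 replicate 5 in the last of these (3.899).

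The library labelled KO sham replicate 2 carried signal of the Ntrk2 probe sets that read low in KO cord. In SDs of the WT sham arrays from their mean, its probe sets A and B lay at -4.52 and -10.53, Cd59a at 19.7 and Dapk1 at 1.44. The first 3 values argue against a WT array under a wrong label. The SDs come from 4 arrays, 0.03 for Cd59a, and the measures were picked for differing between the genotypes, so the distances are rough. An array with 1 intact and 1 disrupted copy, or an equal mixture of both genotypes, needs values near the middle on the linear scale, and the farthest of 4 positions was 0.55. An equal mixture with RNA of the WT sham arrays would have a caudal Hox mean of 7.76, and the array stood 0.83 above that, at 8.59, near the 8.42 ± 0.29 of the other 3 KO sham arrays, which leaves this open. What the animal's genotype was stays untested.

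The mean of the 4 caudal Hox genes was lower in the WT sham group than in any other group. Single injured arrays were as low. WT day 3 replicate 3, at 5.92, and KO day 3 replicate 3, at 5.84, lay within the WT sham range of 4.94 to 6.12. KO day 3 replicate 4 was at 6.14. Low values are thus not particular to WT sham arrays. Tissue from a more rostral level could lower the WT sham mean. Among 19 other Hox genes the rank correlation of the sham difference with the paralog number was 0.182 (permutation p = 0.452), which leaves that open. A genotype effect at every time point does not account for the low WT sham mean, as the mean difference at days 1, 3 and 7 was 0.106 of that at sham (0.061 to 0.148 with single arrays left out). Muscle taken along with the KO sham tissue does not either, as far as the arrays can be matched. The 2 WT sham arrays with a muscle mean of 8.93 and 8.54 exceeded the lowest KO sham array, at 7.63. Their Hox means still lay below every KO sham array, the highest by -1.96. The other KO sham arrays had more muscle signal than these, from 9.46 to 10.65. Nerve root in the KO sham tissue stays open, with the Schwann cell list at 5.74 ± 1.08 against 4.60 ± 0.23 in WT sham (n = 4 each), though the library labelled KO sham replicate 2 had 4.26, below every WT sham array, and a Hox mean of 8.59, and a genotype effect limited to uninjured cord stays open as well, both untested.

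The cell cycle lists were lower in KO cord at day 1. A smaller response of all genes alike would lower early genes too, but 163 genes that rose over 2-fold by day 1 in the mean of both genotypes and fell by day 3 had a median KO minus WT difference of 0.043 (-0.01 to 0.155 with single arrays left out), so a smaller response of part of the genes stays open, beside a slope of 0.887 and 839 rises and 369 falls of at least 2-fold in KO against 1000 and 487 in WT. An earlier stage of the response in the KO tissue fits, as 75 genes of the lists other than cell cycle that rose over 2-fold from day 1 to day 3 had a median of -0.348 (-0.498 to -0.287 with single arrays left out), with 82.667% of them lower. Those lists include activated macrophage, complement, homeostatic microglia and fibroblast, which camera had called lower in KO on the same arrays. The median is not independent of those calls, so it cannot decide for an earlier stage. Another time of day or level of stress hormone stays open, as the KO minus WT difference of 0.807 in a list of 12 glucocorticoid-responsive genes decides nothing, its genes having been chosen after their values were seen. An effect of genotype on cell division stays open as well, since no test here separates it from a delay.

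The genotype difference in the injury response had 17 genes at day 1 and 1 at day 7. Probe sets with several gene symbols or none, 3649 of them tested, passed in 1832 cases in WT cord at day 3, 736 higher and 1096 lower, and in 5 cases between the genotypes at day 1.

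Other splits of the same arrays exchange labels between the groups compared. Some differ from the real grouping by few arrays and keep much of a true difference. The highest other count is therefore not the level expected without any difference. The real grouping counts among the splits, so a count of 1 means that no other split had as many. For injury in WT cord that count was 1 of 100 splits at day 1 (7140 genes, highest other 6221), 1 of 35 at day 3 (8018, highest other 3029) and 1 of 35 at day 7 (7088, highest other 1904). In KO cord it was 1 of 35 at day 1 (6124, highest other 8), 1 of 100 at day 3 (8359, highest other 7989) and 1 of 35 at day 7 (6540, highest other 2). Between days it was 1 of 100 for day 3 against day 1 (7242, highest other 5514) and 1 of 100 for day 7 against day 3 (5535, highest other 4510). Chance is excluded for these at the resolution of the splits.

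Between the genotypes the count was 2 of 35 splits at sham (8 genes, highest other 67), so chance is not excluded there, and another split with several times the real count points to a structure of the samples. At day 1 it was 1 of 100 (103 genes, highest other 96), which excludes chance only at the resolution of the splits drawn, and the highest other split came close. At day 3 it was 31 of 100 (4 genes, highest other 3704), so chance is not excluded and the splits point to a structure of the samples. At day 7 it was 1 of 35 (4 genes, highest other 3). For the genotype difference in the injury response it was 4 of 100 at day 1 (17 genes, highest other 34), 100 of 100 at day 3 (0 genes, highest other 7) and 9 of 100 at day 7 (1 gene, highest other 1), so chance is excluded at day 1 only.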

How the results depend on the processing

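Alternatives were compared with the fit described in the report by the number of genes passing, the direction of list calls and the Ntrk2 differences. The last 4 described were added after the data had been seen. Except where stated, the cause of a change was not tested.

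A shift to a common median left 2 genes for KO against WT at day 3. Quantile normalisation moved no count by over 1.5 times. Without the intensity filter the counts were 22 for KO against WT at sham, 9 at day 7, and 3 and 4 for the genotype difference in the injury response at days 3 and 7. With the stricter filter the last of these was 0. With the mean of all probe sets the genotype difference at day 1 had 10 genes, and the values of Eif2s3y in WT at day 1 (-0.261) and of Ntrk2 for the genotype difference at day 1 (-0.1956) turned direction. The Ntrk2 mean takes in probe sets A and B, which read low in KO cord. With every probe set tested more features enter by construction, and the counts were 13002, 15187 and 13143 in WT and 10953, 15930 and 11601 in KO at days 1, 3 and 7, 13, 9 and 10 for KO against WT at sham, day 3 and day 7, and 13100 and 10018 between days. Low signal over background limits genes that only these fits take in.

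Replicate numbers do not pair the arrays. Of 113 pairs with the same number the residual correlation ran from -0.513 to 0.557 with a median of 0.004, against -0.015 in 392 other pairs, and 6 of 34 arrays were nearest to their own number. With the number as a block KO against WT had 166 genes at day 1, all 103 among them, and 2 at day 7.

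With only the groups of a comparison in the fit, KO against WT had 1 gene at sham, 65 at day 1, 0 at day 3 and 21 at day 7, and the genotype difference at day 7 had 57. The Ntrk2 differences at sham stayed at -4.816 and -5.453 but did not pass, at adjusted p = 0.728 and 0.714. The trended and robust prior left 2 genes for KO against WT at day 7. Array weights gave 65, 310, 2 and 233 genes for KO against WT at sham and days 1, 3 and 7, and 105 and 56 for the genotype difference at days 1 and 7. At day 3 they turned 3 list directions upward, neuron (adjusted p = 0.5796) and clock (0.7739) for KO against WT, and neuron (0.4999) for the genotype difference, and Cdk1 for KO against WT at day 3 turned to -0.09315. With an estimated correlation 18 of 196 list calls held, and with fry 132.

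Left out singly, arrays moved the counts as follows. In WT cord they ran from 6544 to 7583 at day 1, 7577 to 8128 at day 3 and 6527 to 7568 at day 7, and in KO cord from 4986 to 6627, 7951 to 8753 and 5851 to 7027. For KO against WT they ran from 4 to 11 at sham, 49 to 208 at day 1, 2 to 32 at day 3 and 2 to 9 at day 7. For the genotype difference they ran from 13 to 38, 0 to 1 and 1 to 2 at days 1, 3 and 7. Between days they ran from 6882 to 7571 and 5000 to 5898, and list calls from 189 to 205. Slopes ran from 0.8394 to 0.9266, 0.9837 to 1.093 and 0.8649 to 0.9398. For Ntrk2 probe set A the differences ran from -6.112 to -4.061 at sham, -6.333 to -6.007 at day 1, -7.016 to -6.563 at day 3 and -6.579 to -6.389 at day 7. For probe set B they ran from -6.894 to -4.973, -6.337 to -6.257, -6.403 to -6.145 and -6.938 to -6.852.

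Without the library labelled KO sham replicate 2 the genotype difference had 28, 1 and 2 genes at days 1, 3 and 7. Without WT day 3 replicate 2 and KO day 3 replicate 3, the arrays farthest from their groups, KO against WT had 259, 2 and 8 genes at days 1, 3 and 7, and the genotype difference at day 1 had 45. With the muscle list mean as a covariate KO against WT at day 7 had 2 genes, and the muscle list turned upward in KO at day 1 (adjusted p = 0.9864) and downward for KO against WT at sham (0.7336), which is by construction, as the covariate is that list's own mean.

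The caudal Hox mean as a covariate is by construction nearly confounded with the WT sham group. With it KO against WT had 867 genes at sham and 11 at day 3, the genotype difference had 1346 at day 1 and 146 at day 7, the slopes were 0.6042, 0.7467 and 0.6703, and probe set A at sham was -4.845 (adjusted p = 0.0501). List directions turned upward at sham for G2/M (adjusted p = 0.09029), macrophage (0.0002193) and complement (0.0275). For the genotype difference at day 1 interferon turned downward (0.9373). At day 3 G1/S (0.01726), macrophage (0.273), cytokines (0.05804), complement (0.4362) and interferon (0.01166) turned downward, and neuron (1.37e-08) and clock (0.6526) upward. At day 7 interferon turned downward (0.2195). Bdnf in WT at day 1 turned to -0.08459, and at sham Hoxd10 turned to -0.9826 and Hoxd9 to -0.1484, both part of the covariate itself.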

Other observations

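Of 13 endothelial genes in WT cord 10 rose and 1 fell at day 1, 11 rose at day 3 and 4 at day 7 (the same counts adjusted over the list alone), with the adhesion gene Cdh5 at least 5.01-fold, 10.1-fold and 2.52-fold higher, the last a call lost in 1 of 34 fits with 1 array left out. Camera had adjusted p = 0.0146, 7.29e-05 and 0.0861, and with an estimated correlation adjusted p = 0.471, 0.24 and 0.598. Of 10 oligodendrocyte precursor genes 3 rose and 2 fell at day 1, 4 and 1 at day 3 and 5 and 1 at day 7 (the same adjusted over the list alone), with the proteoglycans Vcan 3.15-fold and Cspg4 3.37-fold higher at day 3, and camera adjusted p = 0.658, 0.216 and 0.0648. WT day 3 replicate 2 stood apart in this list and in the ependymal list. Of 10 ependymal genes 5 fell and 1 rose at day 1, 4 and 2 at day 3, and 1 and 4 at day 7 (the same adjusted over the list alone), with the cilium gene Ccdc153 at -2.62 ± 0.26 at day 1 and the secreted Mia 6.55-fold higher at day 7, and camera adjusted p = 0.0249, 0.403 and 0.329, the first with adjusted p = 0.433 with an estimated correlation. Of 7 Schwann cell genes 6 rose at day 1 and 5 at days 3 and 7 (the same adjusted over the list alone), with Dhh, a signal of Schwann cells, at least 2.21-fold higher at day 1, and camera adjusted p = 0.00744, 0.0288 and 0.0299, which became adjusted p = 0.382, 0.402 and 0.383 with an estimated correlation.

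Of 12 iron and heme genes in WT cord 8 rose and 2 fell at day 1, 9 and 1 at day 3, and 7 and 2 at day 7 (the same adjusted over the list alone), with the phagosomal metal transporter Slc11a1 at least 6.18-fold, 16.7-fold and 20.6-fold higher. Camera had adjusted p = 0.00612, 0.00239 and 0.0328, and with an estimated correlation adjusted p = 0.117, 0.0933 and 0.262. Of 15 heat shock genes 7 rose and 3 fell at day 1 (7 and 4 adjusted over the list alone), with the chaperone Hspb1 28.1-fold higher, and camera adjusted p = 0.02 became adjusted p = 0.259 with an estimated correlation. Of 12 clock genes 8 fell and 2 rose at day 1 (the same adjusted over the list alone), with Per3 at -1.08 ± 0.17 and Hlf at -1.61 ± 0.26, and camera adjusted p = 0.128. Of 12 neutrophil genes 3 rose at day 1 (3 adjusted over the list alone), with Lcn2, an iron-binding lipocalin, 18.6-fold higher, and camera adjusted p = 0.254. No red blood cell gene of 3 passed at day 1 (0 adjusted over the list alone), with the erythrocyte anion exchanger Slc4a1 at -0.52 ± 0.87 and camera adjusted p = 0.865. Of 3 sex-linked genes 1 rose at day 1, Eif2s3y at 0.38 ± 0.15 (0 adjusted over the list alone), a call lost in 4 of 34 fits with 1 array left out, with camera adjusted p = 0.642. Of 13 cell cycle inhibitors 8 rose and 2 fell at day 1 (the same adjusted over the list alone), with Cdkn1c at -2.12 ± 0.24, and camera adjusted p = 0.0452 became adjusted p = 0.335 with an estimated correlation.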
